A study of Homo sapiens with 3 samples.

How the data were processed

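RNA was measured in 3 stable lines of FaDu, an established human squamous carcinoma cell line of the hypopharynx. Per the labels, the lines carried an empty pCDH lentiviral vector (vector control), pCDH with wild-type Snail (Snail), or pCDH with a mutant Snail (Snail2R). Each group had 1 array. No replicate culture or replicate array was used here, so no p-value, no test and no spread between replicates could be computed, and every difference compares single arrays.

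The intensity values were deposited by the authors as scanner output of Agilent one-colour (Cy3) arrays, extracted with Agilent Feature Extraction 10.5.1.1 per the file headers. Per the file headers, each spot had a processed intensity after background subtraction, mean and local background intensities, outlier flags, a saturation flag and a flag for being well above background. Per the labels, total RNA had been amplified and labelled with Cy3 during in vitro transcription. All 3 arrays lay on 1 slide and belonged to 1 scan, so neither slide nor scan separated the groups. Each array held 58717 non-control spots for 50599 probes, of which 49697 were printed once and 902 were printed 10 times. No spot was saturated (0 on each array). Probe coordinates are those of the files, on build hg19.

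The values compared here were log2 of the processed intensity minus the array's 75th percentile of it. Control spots and spots with an outlier flag (505 on vector control, 550 on Snail and 494 on Snail2R) were left out, and spots of one probe were averaged. A gene took the value of its brightest probe. It counted as measured where that probe was well above background on both arrays compared. A gene above background on only 1 of the 2 arrays was given a bound, the bright value over the higher of the dim probe's own signal and the lowest signal well above background on the dim array, written as at least N-fold. Genes with a measured log2 difference of 1 or more in size were counted as 2-fold higher or lower.

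Gene names came from the files. Of 20738 named genes on the array, 19913 were matched by accession to a RefSeq gene table, 1475 had another current symbol there and 414 had none. The file's names are used in the text. The 20237 probes with no gene name (transcript identifiers, uncharacterised loci and long intergenic transcripts) were left out of the gene counts.

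Technical error was taken from the repeat spots. For probes printed 10 times it was the standard deviation (SD) of the spots over the square root of their number, and for probes printed once it was the spot SD expected at that brightness on that array. These technical standard errors (SEs) cover spot noise within an array and leave out culture, RNA extraction, labelling and hybridisation. The number of arrays limits the precision of every value.

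Before the data were examined, 20 gene lists, the rule for naming genes and 9 of the 10 alternative settings for these values, besides 1 for the bounds, were fixed. The lists were epithelial adhesion and identity, mesenchymal, chemokines, cytokines and growth factors, NF-kappaB targets, interferon-stimulated, leukocyte and macrophage markers, basal keratinocyte and hemidesmosome, squamous differentiation, extracellular proteases and inhibitors, stemness-linked, proliferation, p53 targets, hypoxia and glycolysis, unfolded protein and amino acid stress, cholesterol synthesis, TGF-beta response, ribosomal proteins, replication-dependent histones, and genes tied to Snail by earlier work. Of their 724 symbols, 720 were on the array. For each list the median log2 difference of its measured members was set beside the range holding 95% of 10000 random lists of the same size, drawn from measured genes in the same of 10 classes of mean signal. That range describes these arrays and is not a p-value. With 60 list medians, about 3 would lie outside it by chance. The SD given with a list's median comes from resampling its members 2000 times.

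The rule for named genes took SNAI1 first. It then took the 12 highest and 12 lowest genes per comparison with a mean signal at or above the 25th percentile, probes of one sign, and a difference still 2-fold under another background correction. It added the 4 largest bounds in each direction, up to 4 members of each list that were at least 2-fold apart, and CDH1, VIM, TNF, CCL2, CCL5, IL8, IL6, ERCC1, MMP9, ZEB1 and SNAI2 in any case. The report names a part of the genes this rule takes. Other list members appear with their values as examples, and were picked after those values were seen.

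The alternatives were normexp background correction (offset 50) on mean and background intensities, median scaling, quantile and cyclic loess normalization, the mean over a gene's probes, no filter on dim probes, genes measured on all 3 arrays, the brighter part of the genes, outlier spots kept, and the 5th percentile of signals well above background as the limit for bounds. Scaling to 10 spike-in probes was added after the data had been seen. Leaving out replicates and fitting the slide as a block were not possible with 1 array per group.

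The counting steps were tested on simulated data built for Snail minus vector control over 16299 genes. With noise of 1 SD for all genes (0.141, from vector control), all 50 genes set 3-fold apart and all 50 set 4-fold apart were counted in the right direction, as were 31 of 50 set 2-fold apart and 0 of 50 set 1.5-fold apart. That noise leaves almost no room for false counts, so the same changes were simulated again, after the results had been seen, with the repeat-spot deviations of each array by brightness. Then 49 of 50 set 4-fold apart, 48 of 50 set 3-fold, 24 of 50 set 2-fold and 0 of 50 set 1.5-fold apart were counted, and so were 296 unchanged genes. This treats each gene as a single spot. Of 200 unchanged random lists with the first noise, which was independent between genes, 188 lay inside the 95% range. Correlations between comparisons that share the control array were set beside 100 simulations of unchanged arrays. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.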

Results

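Snail (SNAI1) is a zinc-finger repressor that binds E-box elements and lowers transcription of epithelial genes such as CDH1. Genome-wide transcript levels were measured in FaDu cells carrying an empty vector, wild-type Snail or the mutant Snail2R, with 1 array each. From general knowledge of the field, the 2R form has arginine in place of a pair of lysines that can be acetylated, which the files do not show. The design asks what wild-type Snail does to transcript levels, what the mutant does, and where they part. Of the non-control spots, 64.8% were well above background on the vector control array, 63.1% on the Snail array and 61.5% on the Snail2R array. Differences are log2 values of single arrays without a replicate check, and ± marks the technical SE from repeat spots. Spike-in scaling, an alternative, would add 0.46, 0.23 and 0.23 to every difference of Snail minus vector control, Snail2R minus vector control and Snail minus Snail2R. It would move the random ranges of the lists by the same amounts, so a list's standing against other genes stays the same under it.

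The SNAI1 probe gave differences from vector control of 0.32 ± 0.18 in Snail and 0.66 ± 0.15 in Snail2R. It lies in the 3' untranslated part of the transcript (chromosome 20, 48605170 to 48605229), which an introduced coding sequence need not carry, so it checks neither construct. The labels of the 3 lines were therefore taken as given.

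Wild-type Snail against vector control was the widest contrast, with 781 genes 2-fold or more higher and 694 lower among 15591 measured (9.46%), a split that was 1954 higher and 319 lower under spike-in scaling. Of 52 epithelial genes 28 were lower, including CDH1, which encodes E-cadherin, at -1.36 ± 0.03 (chromosome 16, 68869214 to 68869273). The median of mesenchymal genes was higher, and VIM, the intermediate filament vimentin, was at least 108-fold higher (chromosome 10, 17278347 to 17279256) because it was not well above background in vector control. Secreted signalling genes were among the highest in Snail, with CXCL11 at 5.08 ± 0.38, CCL3 at 5.01 ± 0.42, INHBA at 4.94 ± 0.04 and CSF3 at 4.33 ± 0.29, while IL11 was 32.0-fold higher. KRT4 (-5.21 ± 0.12) and KRT13 (-4.52 ± 0.10), keratins of stratified mucosa, were lowest among the measured genes that passed the naming rule. The lineage factor SOX2 stood at -4.05 ± 0.14.

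Of 52 measured epithelial genes, 28 were 2-fold or more lower in Snail than in vector control and 0 higher, with a median of -1.06 (SD 0.11), against a random range of -0.22 to 0.04. KRT19 stood at -2.52, ELF3 stood at -2.31, and the tight junction genes OCLN and CLDN3 stood at -2.21 ± 0.58 and -2.19 ± 0.44. The mesenchymal list had 14 of 33 members higher and 2 lower, with a median of 0.82 (SD 0.22). COL6A2 (3.40), TAGLN (3.16), ITGA5 (2.63), ACTA2 (2.59) and ZEB1 (1.91 ± 0.30) were higher. The related repressor SNAI2 was lower, at -1.35 ± 0.21.

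Interferon-stimulated genes, which encode antiviral proteins, were higher together in Snail. All 40 were measured and all 40 had positive differences, 26 of them 2-fold or more, with a median of 1.18 (SD 0.13) against a random range of -0.26 to -0.02. RSAD2 (3.40 ± 0.18), CMPK2 (2.70), MX2 (2.63) and ISG20 (2.39) led this list. Among NF-kappaB targets 15 of 35 were higher and 1 lower, with a median of 0.77 (SD 0.20). PTX3 (3.63), TRAF1 (3.09) and the adhesion molecule ICAM1 (2.23 ± 0.02) were examples.

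Chemokine genes went apart in Snail, with 8 of 20 measured members higher, 1 lower and a median of 0.01, inside the random range of -0.25 to 0.20. CXCL10 stood at 3.56 ± 0.19, CCL4 at 3.28 ± 0.37, the monocyte attractant CCL2 at 2.12 ± 0.15 and CCL5 at 2.31 ± 0.09. Of the neutrophil attractants, IL8 stood at -0.16 ± 0.09 and CXCL1 at -1.03. Of 48 cytokine and growth factor genes 17 were higher and 5 lower, with a median of 0.25 (SD 0.25). LTB (3.35 ± 0.09), IL6 (2.02 ± 0.09) and TNF (1.32 ± 0.25) were higher and the antagonist IL1RN was lower (-2.11).

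Squamous differentiation genes had 13 of 38 members lower and 1 higher in Snail (median -0.57, SD 0.24, but -0.10 under spike-in scaling and -1.13 among the brighter part of the genes), with LY6D at -3.95 ± 0.18 and SERPINB13 at -3.21 ± 0.31. Basal keratinocyte genes had 8 of 26 lower and 3 higher (median -0.46), with KRT15 at -3.67 and KRT5 at -2.21. Under spike-in scaling, which moves the random range alike, this median was 0.0025. Cholesterol synthesis genes had 5 of 25 lower and 0 higher (median -0.50, SD 0.11), and 24 of 25 were negative, although the median was -0.041 under spike-in scaling. TGF-beta response genes had 4 higher and 2 lower of 25 (median 0.52, but 0.33 under normexp and 0.98 under spike-in scaling), with BAMBI at 1.43 and ID1 at -1.42. Extracellular proteases and inhibitors had 8 higher and 8 lower of 29 (median 0.19), with TIMP2 at 2.82 and MMP3 at 2.71 ± 0.44. MMP9 was higher, at 1.49 ± 0.03.

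The remaining list medians lay inside or just outside their random ranges in Snail against vector control. None of 40 proliferation genes was 2-fold apart (0 higher, median -0.03). The hypoxia and glycolysis median of 0.06 lay just above its random range of -0.26 to 0.03 and was -0.068 among the brighter part of the genes. Medians were 0.05 for p53 targets, 0.02 for unfolded protein and amino acid stress, and -0.08 for stemness-linked genes. In the stemness-linked list NT5E, the ecto-nucleotidase CD73, stood at 4.03 ± 0.13 and NOTCH3 at -2.42. Leukocyte and macrophage markers had a median of 0.02 over 15 measured genes, with CD68 at 2.85 and CD3D at -1.07. Ribosomal protein genes (median -0.33) and replication-dependent histones (-0.32) lay just below their random ranges. Both were positive under spike-in scaling, at 0.13 and 0.14, which moves the random ranges alike. Genes tied to Snail by earlier work, which include genes reported to go either way, had 6 higher and 5 lower of 22, with ERCC1 at -0.02 ± 0.09.

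A further 260 genes were above background in Snail and not in vector control with a bound of 2-fold or more, and 217 the other way. The matrix gene THBS2 was at least 116-fold higher in Snail. Where 2-fold genes had further measured probes, 297 of 358 of these (83.0%) had the same sign and 152 were also 2-fold apart. The Snail array was noisier, with 77 of 3469 repeat-spot pairs (2.22%) 2-fold or more apart, against 13 of 3499 (0.372%) on vector control and 11 of 3421 (0.322%) on Snail2R. Part of it went with position: spots of the 44 noisiest repeated probes of the Snail array (median log2 signal 6.71, against 11.13 for the others) lay -0.50 from their probe's mean in the left part of the array and 0.51 in the right, against -0.0014 and 0.0014 for other probes. These probes were picked for a spot SD above 0.4. The other arrays had fewer such probes and a smaller tilt the same way, -0.23 and 0.32 on vector control (23 probes) and -0.26 and 0.25 on Snail2R (10 probes). The share of genes with a probe printed once that were 2-fold apart was 8.55% to 10.3% across 8 strips of the array. With such deviations of single spots a simulation counted 296 unchanged genes as 2-fold apart, so part of the 1475 may come from them. Genes dim in vector control with a probe printed once therefore rest on weak ground, among them CXCL11, CCL3, CCL4, CSF3, IL11 and VSTM1 (5.62 ± 0.34), the highest measured gene that passed the naming rule. The bounds of THBS2 and VIM also rest on 1 spot per array, and their size depends on the background limit chosen.

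In Snail2R against vector control 10 of 52 epithelial genes were 2-fold lower, and 4 interferon-stimulated and 2 chemokine genes were 2-fold higher. The cytokine genes IL11 (4.66 ± 0.35), INHBA (4.40 ± 0.04) and CSF3 (4.21 ± 0.29) were near their values in Snail, as was NT5E (3.68 ± 0.13). KRT4 stood at -5.92 ± 0.13, SOX2 at -4.23 ± 0.12 and KRT13 at -4.07 ± 0.09. CDH1 stood at -0.39 ± 0.03, below the 2-fold threshold. In all, 480 genes were 2-fold or more higher and 447 lower among 15431 measured (6.01%), or 728 and 279 under spike-in scaling.

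Epithelial genes had no member 2-fold higher in Snail2R (0 of 52; median -0.39, SD 0.09, but -0.15 under spike-in scaling and -0.28 among the brighter part of the genes), with ELF3 at -2.01, CLDN1 at -1.90 and KRT19 at -1.72. Mesenchymal genes had 6 of 32 higher and 1 lower (median 0.16, SD 0.17, but 0.39 under spike-in scaling). VIM was at least 25.1-fold higher, ITGA5 stood at 1.86 and EMP3 at 1.61, while ZEB1 was at 0.50 ± 0.33 and S100A4 at -1.80. Squamous differentiation genes had 13 of 35 lower and 2 higher (median -0.42), and basal keratinocyte genes 6 of 26 lower and 4 higher (median -0.12).

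Interferon-stimulated genes had 4 of 40 members 2-fold higher in Snail2R (ISG20 at 1.86, RSAD2 at 1.62, IFIT2 at 1.13 and MX2 at 1.12) and a median of 0.32 (SD 0.08). NF-kappaB targets had 6 of 34 higher and 1 lower (median 0.48, SD 0.21), with PTGS2, the inducible cyclooxygenase, at 2.15 ± 0.05. This median was 0.05 among the brighter part of the genes. Of 18 chemokine genes 2 were higher (CCL3 at 2.76 ± 0.43 and CXCL11 at 2.36 ± 0.39) and 3 lower, with a median of -0.15. CCL5 stood at 0.75 ± 0.08, IL6 at 0.73 ± 0.08, TNF at -0.47 ± 0.31 and IL8 at -0.26 ± 0.09. CCL2 was near the background limit on both arrays, with 6 of 10 spots well above background in vector control and 2 of 8 in Snail2R. Its levels there were -3.49 and -3.79, so no direction is drawn. Cytokine and growth factor genes had 14 of 48 higher and 7 lower (median -0.04, but 0.25 among the brighter part of the genes), with the death ligand TNFSF10 at -2.01.

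Cholesterol synthesis genes had 7 of 24 members lower and 0 higher in Snail2R, with a median of -0.68 (SD 0.08). INSIG1 (-2.01 ± 0.10) and MVK (-1.15) were lower. Replication-dependent histones had a median of -0.23, which was 0.0060 under spike-in scaling. The medians of p53 targets (-0.24), TGF-beta response (0.18), proteases and inhibitors (0.18) and hypoxia and glycolysis (0.12) lay outside their random ranges by small amounts. Among the brighter part of the genes TGF-beta response was -0.089 and p53 targets -0.029 (-0.0078 under spike-in scaling), and hypoxia and glycolysis was -0.038 with the mean over probes. ANGPTL4 stood at 3.38, MMP3 at 3.32 ± 0.42 and MMP9 at 1.37 ± 0.02. Medians inside the random range were 0.06 for proliferation, 0.03 for unfolded protein stress, -0.06 for stemness-linked genes, -0.05 for leukocyte markers, -0.10 for ribosomal proteins and 0.02 for genes tied to Snail. The Snail2R medians given above for chemokine, cytokine and growth factor, and basal keratinocyte genes lay inside too. Those of epithelial, squamous, NF-kappaB, interferon-stimulated, cholesterol and histone genes lay outside, and the mesenchymal median lay just above its range. Bounds of 2-fold or more were found for 186 genes higher and 188 lower, and 187 of 235 further probes of 2-fold genes (79.6%) had the same sign and 70 were also 2-fold apart.

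**Figure D1:**
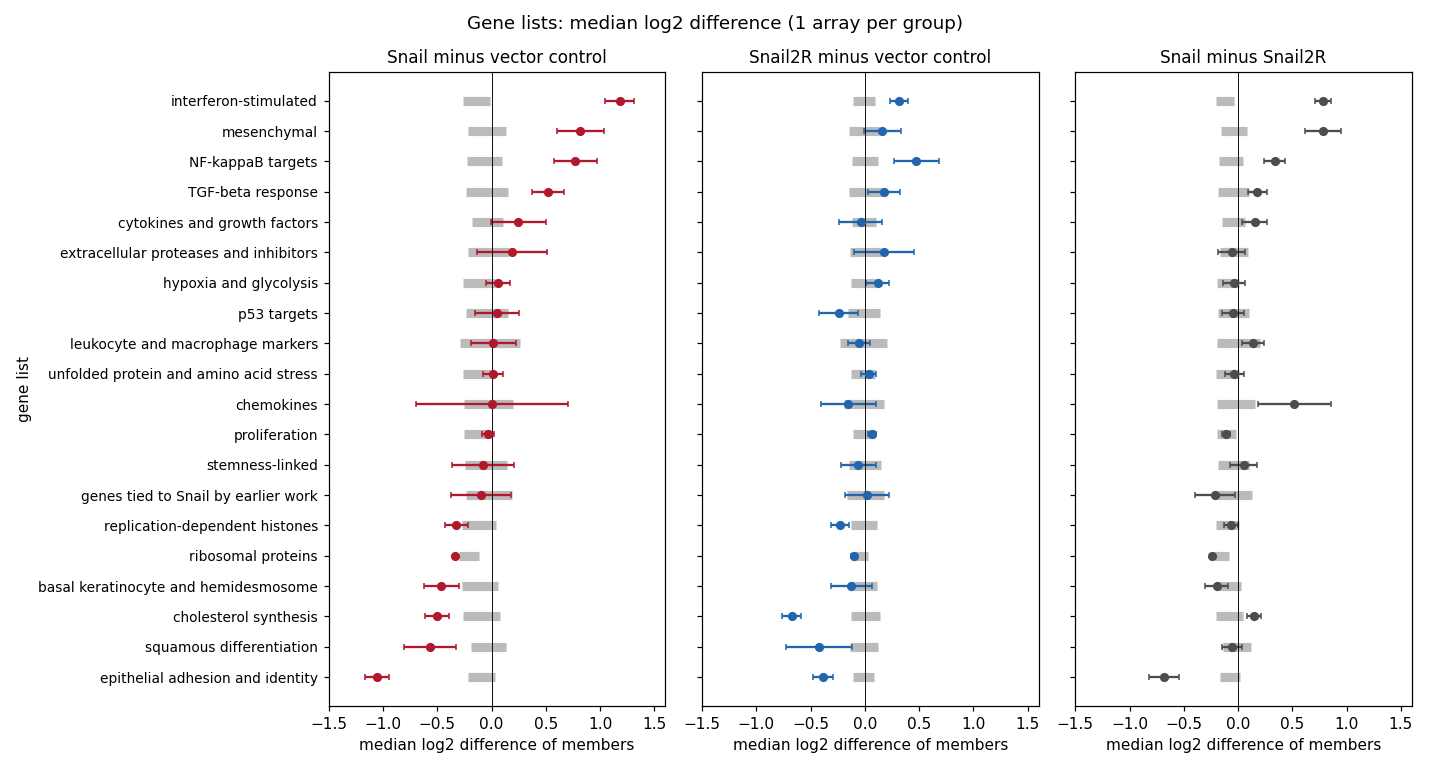
Median log2 difference of each of the 20 gene lists in the 3 comparisons (x axis, log2), with the list names on the y axis. Points are medians over measured members, bars are ± 1 SD from resampling the members, and grey bands hold 95% of 10000 random lists. Interferon-stimulated genes stood at 1.18, 0.32 and 0.79 and epithelial genes at -1.06, -0.39 and -0.68. Under spike-in scaling the histone medians of both comparisons with vector control and the ribosomal and basal keratinocyte medians of Snail against vector control turned positive, as did that of genes tied to Snail in Snail minus Snail2R and some medians inside their ranges.

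Direct comparison of the Snail and Snail2R arrays gave 369 genes 2-fold or more higher in Snail and 295 lower among 15384 measured (4.32%), or 686 and 167 under spike-in scaling. This comparison also uses the noisier Snail array. False counts among unchanged genes were not simulated for it, so part of the 664 may come from spot noise. Higher in Snail were 11 of 40 interferon-stimulated and 7 of 18 chemokine genes, with CXCL10 at 2.94 ± 0.14, CXCL11 at 2.73 ± 0.14, BST2 at 2.16 and CCL5 at 1.57 ± 0.08. The complement proteases C1R (3.13 ± 0.09) and C1S (2.66 ± 0.09) were also higher. TNF stood at 1.80 ± 0.26, IL6 at 1.28 ± 0.08 and CCL2 was at least 5.36-fold higher in Snail. Of 52 epithelial genes 15 were lower in Snail than in Snail2R, with OCLN at -1.86 ± 0.59, EPCAM at -1.71 and CLDN7 at -1.57, while CDH1 stood at -0.97 ± 0.03, below the 2-fold threshold.

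All 40 interferon-stimulated genes were again positive in Snail minus Snail2R, 11 of them 2-fold or more (median 0.79, SD 0.07, random range -0.21 to -0.04). Chemokine genes had 7 of 18 higher and 0 lower (median 0.52, SD 0.33), a median that was 0.16 with no filter on dim probes. Cytokine and growth factor genes had 9 of 49 higher and 1 lower (median 0.15), a median that was -0.08 among the brighter part of the genes. NF-kappaB targets had 5 of 34 higher and 0 lower (median 0.34, SD 0.10), with SAA2 at 2.02, PTX3 at 1.87, C3 at 1.82 and ICAM1 at 1.69.

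Mesenchymal genes had 12 of 34 members higher and 0 lower in Snail than in Snail2R, with a median of 0.78 (SD 0.16), or 0.47 with no filter on dim probes. TAGLN stood at 2.48, VIM at 2.11 ± 0.10, COL5A1 at 1.99 and ZEB1 at 1.41 ± 0.23. Epithelial genes had 15 of 52 lower and 0 higher (median -0.68, SD 0.14). Squamous differentiation (median -0.06, but -0.33 among the brighter part of the genes) and proliferation (-0.11) lay inside their random ranges. Cholesterol synthesis (0.14), TGF-beta response (0.18), ribosomal proteins (-0.24) and genes tied to Snail (-0.22) lay outside by small amounts. Under spike-in scaling these were 0.37, 0.41, -0.011 and 0.015, and ribosomal proteins were at -0.091 under quantile and -0.047 under cyclic loess normalization. The other medians inside the range were -0.20 for basal keratinocyte genes, -0.06 for proteases and inhibitors, 0.05 for stemness-linked genes, -0.05 for p53 targets, -0.04 for hypoxia and glycolysis, -0.03 for unfolded protein stress, 0.13 for leukocyte markers and -0.07 for histones. MMP9 (0.12 ± 0.02), IL8 (0.10 ± 0.09) and ERCC1 (-0.29 ± 0.08) were close on both arrays. The highest measured gene that passed the naming rule, LGI4 (5.21 ± 0.34), has a probe printed once. Of 134 further probes of 2-fold genes 104 (77.6%) had the same sign and 50 were also 2-fold apart.

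**Figure D2:**
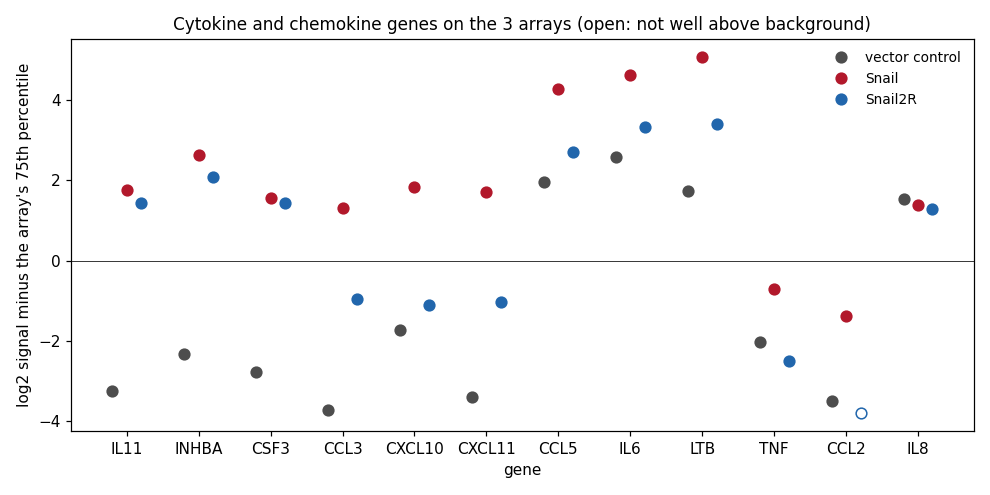
Level of 12 cytokine and chemokine genes on the 3 arrays (y axis, log2 signal minus the array's 75th percentile), with 1 point per array and gene. Open points were not well above background. IL11, INHBA and CSF3 were high in both Snail and Snail2R, while CXCL10, CXCL11, CCL3, CCL5, LTB and CCL2 were higher in Snail than in Snail2R.

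The differences from vector control of Snail and Snail2R were related across the 15222 genes measured on all 3 arrays (Pearson r 0.72, Spearman rho 0.67, across genes, which are not independent replicates). Both differences use the same control array, and simulated unchanged arrays gave r of 0.43 with the repeat-spot noise and 0.50 with a larger noise SD of 0.32. That larger SD came from the spread of Snail minus Snail2R, in which the control array takes no part. Neither simulation therefore limits how far the single control culture or array could have deviated and so produced a shared difference. The covariance was 0.24, against 0.020 and 0.10 simulated. Genes 2-fold higher in both numbered 273, of 756 in Snail and 461 in Snail2R, and 22.9 would be shared by independent lists. Genes lower in both numbered 299, of 656 and 430, against 18.5. Simulated unchanged arrays shared 8.46 and 55.5 genes over both directions, and part of the overlap may come from the shared control. Of the genes higher in Snail, 694 of 756 had a positive difference in Snail2R too, with a median of 0.77 there and 1.43 in Snail. Of those lower in Snail, 639 of 656 were also negative in Snail2R, with medians of -0.92 and -1.40. These genes were picked by their Snail values, which by itself lowers the second median.

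**Figure D3:**
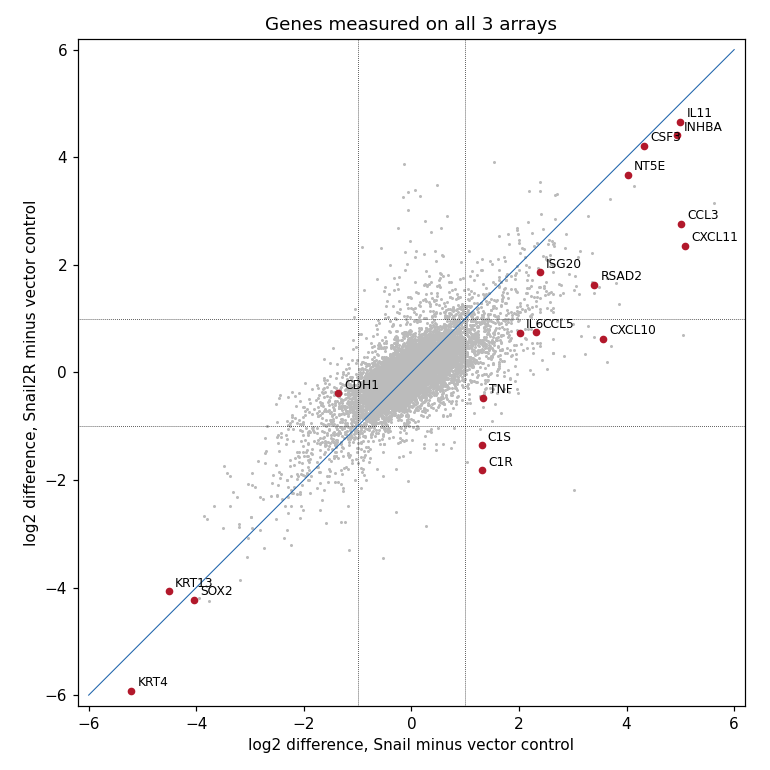
Log2 difference from vector control in Snail (x axis) and Snail2R (y axis) for the 15222 genes measured on all 3 arrays, 1 grey point per gene, with selected genes in red. Dotted lines mark 2-fold and the blue line marks equal differences. KRT4, KRT13, SOX2, IL11, INHBA, CSF3 and NT5E lie near the line, and CXCL10 (3.56 and 0.62) and C1R (1.31 and -1.82) lie far from it.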

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

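No test of a difference was possible with 1 array per group, and the results in this part were picked out by rules applied after the values were known. Among named genes, 7 were at least 2-fold from vector control in opposite directions in Snail and Snail2R, and the difference between the lines was not tested. Higher in Snail and lower in Snail2R were LGI4, with a log2 difference of 5.21 for Snail minus Snail2R, C1R (3.13), GPR37L1 (2.72), C1S (2.66) and VWF (2.33). The other way round were PPARGC1B (-2.22) and KIAA0895 (-2.09). C1R and C1S, neighbouring genes for the proteases that start the classical complement pathway, were above the 75th percentile of signal on all 3 arrays. LGI4, GPR37L1, VWF, PPARGC1B and KIAA0895 were below the 75th percentile of signal in vector control, where the noise of the Snail array weighs more.

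Probes without a gene name were left out of the report's comparisons. Of 7246 measured in Snail and vector control, 239 were 2-fold or more higher and 290 lower. Of 7109 measured in Snail2R and vector control, 209 were higher and 210 lower. The long non-coding transcript LINC00520 stood at 3.43 in Snail.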

How the results depend on the processing

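All alternatives in this part were planned before the data were examined except scaling to spike-in probes, which was chosen after the result was seen. Single arrays leave no spread between replicates, so a list's median counted as moved when it shifted by more than the SD from resampling its members, and a count when it shifted by over 1.5 times. No paired analysis was possible because each group had 1 array, and for the same reason neither leaving out replicates nor a slide block was possible. The 216 named gene differences of 2-fold or more kept their sign under every alternative in which the gene was measured. For the highest and lowest genes the naming rule had required this, and the 2-fold size, under normexp. Its demand for probes of one sign fixed the sign under the mean over probes too. No filter, genes measured on all 3 arrays and the brighter part of the genes leave a gene's value unchanged. They could not alter any of these differences and are no check on them. Under the other alternatives between 193 (spike-in scaling) and 215 (outlier spots kept) of 216 stayed 2-fold. Of the 34 list medians outside their random range, all 34 kept their sign under normexp, median scaling, quantile, cyclic loess, no filter, genes measured on all 3 arrays and outlier spots kept. With the mean over probes 33 did, among the brighter genes 31 and under spike-in scaling 29. Spike-in scaling moves the random ranges alike, so sign changes under it do not bear on a list's standing against other genes. The limit set by signal over background was strongest for dim genes, since only 64.8%, 63.1% and 61.5% of spots were well above background. Except where an alternative tested other genes by construction (no filter, brighter part, background limit), the cause of each shift was not tested.

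The counts of 2-fold genes were 2782 in Snail minus vector control, 2034 in Snail2R minus vector control and 1814 in Snail minus Snail2R with no filter on dim probes, against 1475, 927 and 664. Among the brighter part of the genes they were 492, 255 and 164. Normexp gave 422 for Snail minus Snail2R. With the 5th percentile as background limit, genes with a bound only numbered 263, 227 and 205, against 477, 374 and 330. The correlation of the responses, 0.72, was 0.74 under normexp, 0.62 with no filter, 0.77 among the brighter genes and 0.70 with outlier spots kept. Genes 2-fold apart the same way in both lines, 572, numbered 1162 with no filter and 178 among the brighter genes.

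Spike-in scaling moved the median of all genes to 0.41, 0.23 and 0.19 in the 3 comparisons and gave 2273 genes 2-fold apart in Snail minus vector control. The share of 2-fold genes that were higher was 86.0%, 72.3% and 80.4%, against 52.9%, 51.8% and 55.6%. In Snail minus vector control list medians were then -0.59 for epithelial, 1.28 for mesenchymal, 0.71 for cytokine, 1.24 for NF-kappaB and 1.64 for interferon-stimulated genes. They were 0.48 for leukocyte, -0.10 for squamous, 0.65 for protease, 0.39 for stemness-linked, 0.43 for proliferation, 0.51 for p53, 0.52 for hypoxia and 0.48 for unfolded protein genes. Cholesterol genes stood at -0.041, TGF-beta at 0.98 and Snail-tied genes at 0.37, while basal (0.0025), ribosomal (0.13) and histone genes (0.14) reversed. In Snail2R minus vector control the medians were -0.15 for epithelial, 0.39 for mesenchymal, 0.19 for cytokine, 0.71 for NF-kappaB, 0.55 for interferon-stimulated and 0.18 for leukocyte genes. Basal genes stood at 0.11, stemness-linked at 0.17, proliferation at 0.30, p53 at -0.0078, hypoxia at 0.35 and unfolded protein at 0.27. Cholesterol stood at -0.44, TGF-beta at 0.41, ribosomal at 0.13 and Snail-tied at 0.25, and histones reversed to 0.0060. In Snail minus Snail2R the medians were -0.45 for epithelial, 1.01 for mesenchymal, 0.38 for cytokine, 0.57 for NF-kappaB, 1.02 for interferon-stimulated and 0.36 for leukocyte genes. Basal stood at 0.031, squamous at 0.17, protease at 0.17, stemness-linked at 0.28, proliferation at 0.12, p53 at 0.18 and hypoxia at 0.19. Unfolded protein stood at 0.20, cholesterol at 0.37, TGF-beta at 0.41, ribosomal at -0.011 and histones at 0.16, and Snail-tied genes reversed to 0.015.

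Among the brighter part of the genes, medians in Snail minus vector control were 0.24 for leukocyte, -1.13 for squamous, 0.26 for p53 and -0.077 for unfolded protein genes, and hypoxia reversed to -0.068. For Snail2R minus vector control they were -0.28 for epithelial, 0.25 for cytokine, 0.054 for NF-kappaB, 0.060 for leukocyte and -0.029 for p53 genes, and TGF-beta reversed to -0.089. For Snail minus Snail2R they were 0.30 for leukocyte, -0.33 for squamous and 0.29 for TGF-beta genes, and cytokines reversed to -0.076. With no filter, Snail minus Snail2R gave 0.47 for mesenchymal and 0.16 for chemokine genes.

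Quantile normalization gave 1.32 for interferon-stimulated, 0.064 for proliferation, -0.048 for ribosomal and -0.19 for histone genes in Snail minus vector control. It gave 0.11 for proliferation and 0.047 for ribosomal genes in Snail2R minus vector control. For Snail minus Snail2R it gave 0.44 for NF-kappaB, 0.90 for interferon-stimulated, -0.013 for proliferation, 0.23 for cholesterol, -0.091 for ribosomal and 0.018 for histone genes. Cyclic loess gave 0.085 for proliferation, -0.029 for ribosomal and -0.20 for histone genes in Snail minus vector control, and -0.0047 for ribosomal genes in Snail2R minus vector control. For Snail minus Snail2R it gave 0.45 for NF-kappaB, 0.92 for interferon-stimulated, 0.013 for proliferation, 0.059 for unfolded protein, 0.25 for cholesterol, -0.047 for ribosomal and 0.029 for histone genes. Median scaling gave -0.30, -0.034 and -0.28 for ribosomal genes in the 3 comparisons, and 0.13 and -0.15 for proliferation in Snail2R minus vector control and Snail minus Snail2R. The mean over probes reversed hypoxia in Snail2R minus vector control (-0.038) and gave -0.21 for ribosomal genes in Snail minus Snail2R. Normexp gave 0.33 for TGF-beta in Snail minus vector control and -0.21 for ribosomal genes in Snail minus Snail2R.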

Other observations

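The scaling, leukocyte, common factor, protein amount and copy number tests and the 5 gene lists that follow were chosen after the results were seen, while the tests of interferon transcripts and of spot noise were written down before their values were looked at. Complement genes were higher in Snail, with 6 of 12 measured members 2-fold higher and a median of 1.06, while in Snail2R 4 of 12 were lower and 1 higher, with a median of -0.45. This list was built after C1R and C1S had been seen to go opposite ways, so it partly restates them. C4B (1.55) and C3 (1.51) were higher in Snail, and CFB (-1.34) and CFI (-1.33) were lower in Snail2R, while the complement inhibitor CD55 was higher in both (2.09 and 2.29). Guanylate-binding proteins, which interferons induce, had medians of 1.58 in Snail and 0.20 in Snail2R, with GBP5 at 3.85 and 1.28. The Snail2R median lay inside its random range of -0.29 to 0.33. Class I antigen presentation genes had medians of 0.74 and 0.12, with HLA-F at 1.31 and TAP1 at 1.04 in Snail. TAP1 and PSMB9 also belong to the interferon-stimulated list, so this list partly restates that one.

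As a list, targets of NRF2, the oxidative stress regulator, were lower in both lines, with 10 of 23 lower in Snail (median -0.84) and 6 of 23 in Snail2R (median -0.56). The fall was not uniform, since TXNRD1 (-0.05 and 0.19) and GCLM (0.04 and -0.07) hardly differed from control. GPX2 (-3.80 and -2.72), AKR1B10 (-2.98 and -2.70) and ALDH3A1 (-3.05 and -3.44) were the lowest. The Notch pathway list had 6 of 16 members lower and 0 higher in Snail, among them NRARP (-3.37), NOTCH3 (-2.42) and JAG2 (-1.84), yet its median of -0.16 lay inside the random range. In Snail2R 4 of 16 were lower, with a median of -0.28, outside its random range of -0.19 to 0.18. Both the NRF2 and Notch lists were chosen after genes such as GPX2 and NRARP had been seen to be low, so they partly restate them.

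Interferon-stimulated genes were higher in Snail than in vector control. Under quantile and cyclic loess normalization, 2 settings that do not shift all genes alike, the list's median minus that of all genes was 1.30 or more (SD 0.13), which argues against scaling that depends on brightness. RNA from leukocytes was weighed with 5 abundant transcripts, of which 3 (PTPRC at 0.02, TYROBP at -0.41 and FCER1G at -0.08) lay more than 3 technical SEs below the list's median, while LAPTM5, at least 16.1-fold higher, and CORO1A, 2-fold higher, went with it. These 3 already gave signal in vector control (levels of -1.10, -0.49 and 3.28), where a small leukocyte share could hardly raise them. The test therefore does not decide. The design itself names no source of leukocytes, since all 3 lines were of FaDu, an established carcinoma cell line. Of 17 interferon genes 4 were above background and 2-fold higher in Snail. These were IFNL3 (2.63), IFNB1 (at least 4.34-fold, as it was not above background in vector control), IFNL1 (1.99) and IFNL2 (1.95, nearly identical to IFNL3 in sequence). IFNE was lower (-1.37). In Snail2R, where the list's median was only 0.32, IFNL3 (2.38), IFNL2 (1.08) and IFNL1 (1.06) were also higher. IFNB1 was above background there too, at a level of -3.18 against -2.03 in Snail. Because IFNL3 and IFNB1 were dim in vector control (levels of -3.30 and -4.15), their values rest on weak ground. Interferon made by the cells may underlie part of the higher genes, as a hypothesis that the IFNL3 value in Snail2R weakens, and viral delivery, clone or passage stays open because each group had 1 array.

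Of 13 lists outside their random range in Snail, 11 lay less far from control in Snail2R, which picking them by their Snail values favours. Cholesterol and hypoxia genes lay further, as did several lists outside these 13. Unlike a list's standing against other genes, this distance and the count of 11 depend on the scaling. Under spike-in scaling basal keratinocyte genes lay further in Snail2R (0.11, against 0.0025 in Snail) and ribosomal genes about equally far (0.13 in both). Hypoxia genes then lay less far in Snail2R (0.35, against 0.52), and cholesterol genes again lay further (-0.44, against -0.041). Spot noise of the Snail array was weighed on 635 genes with repeatedly printed probes, whose median absolute difference from control was larger in Snail by 0.072 (SD 0.012, 0.27 against 0.20), which argues against it as the whole account. A single common multiple of the Snail medians was left by 1 of 13 lists beyond an interval adjusted for their number. This was cholesterol synthesis (-0.49 in Snail and -0.68 in Snail2R over the same genes), and the other 12 stayed within theirs. The multiple, 0.37, was the median ratio of these same lists, which also depends on the scaling, and the intervals were wide. Even cytokine genes (ratio -0.16) and hypoxia genes (1.84) stayed within. The test therefore neither shows nor excludes a weaker action of the mutant on most groups. An earlier form of this test used only lists picked for their values and was replaced. A different amount of the introduced protein cannot be told apart from a different action, since the SNAI1 probe (-0.33 ± 0.16 for Snail minus Snail2R) lies outside the coding sequence.

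Genes of a chromosome region could differ together through copy number. In windows of 50 neighbouring genes, the strongest median for Snail minus vector control was 0.42 (chromosome 1, 143897141 to 150280643), and 3 of 5000 shuffled gene orders reached it. For Snail2R minus vector control it was -0.27 (chromosome 2, 136598217 to 166731329), reached by 9 of 5000. For Snail minus Snail2R it was 0.26 (chromosome 7), reached by 27 of 5000. Each shuffled order gave its largest window, so these shares already cover all windows. In the 3 comparisons 3, 3 and 1 windows lay beyond the 95th percentile of these largest windows. Neighbouring genes thus differed together in places more than shuffled orders would give. The rule set for copy number was stricter, a window beyond the largest of 1000 shuffles in each of 5 sets. For Snail minus vector control 3 of 5 sets had one, and for Snail2R minus vector control 0 of 5 did. A first run of 100 shuffles had given counts that varied with the random draw. Copy number as the cause was not decided. Neighbours that share regulation or sequence would give such windows too.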
